A study of Phaeodactylum tricornutum with 6 samples.

How the data were processed

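RNA sequencing libraries of 6 samples of Phaeodactylum tricornutum were analysed, 3 untreated and 3 treated with tetracycline hydrochloride at 4 mg/L. Groups were taken from the treatment label of each sample and the names A, B and C from the sample titles. Per the labels' protocols, RNA was extracted with Trizol and libraries were made with an Illumina TruSeq RNA kit, which does not mark the strand, so reads of overlapping and antisense genes cannot be told apart. Per the submitters' processing notes, CASAVA 1.7 and Bowtie 0.12.2 were used, and the builds named there are the mouse builds mm10 and GRCm38, which cannot hold the diatom gene IDs of the table. The build, the annotation, the read counter and the normalisation tool used for this table are not given in the sources used here, so no coordinates are reported.

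The authors deposited a table of 11796 genes with 1 signal per gene and library. In each library all non-zero values (100%, within 0.01) were whole multiples of 1 step, so the deposited signal is a gene read count divided by 1 size factor per library, and whole reads were recovered by dividing by that step. The deposited factors equalled the median-of-ratios size factors that DESeq2 gives on the recovered reads, from 0.834 in untreated A to 1.14 in tetracycline C. Recovered reads summed to 15806015 to 18328956 per library. At these depths a count of 3 reads corresponds to a normalised value of 2.63 to 3.60.

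The design fixed beforehand named tests for counts and for length- or depth-normalised values, and not for counts divided by size factors. The test for normalised values was used: limma 3.58.1 in R 4.3.3 with trend and robust variance moderation on log2(value + 1), over the 11505 genes with a value of at least 1 in at least 3 libraries, two-sided, with Benjamini-Hochberg adjustment and a threshold of 0.05. Fold changes are on this log2(value + 1) scale, which understates changes of low genes, and a fold is 2 to the power of the log2 fold change. Errors of log2 fold changes are standard errors from limma, and errors of values are SDs over 3 libraries. Nothing in the labels says that the samples came from separate cultures, so p-values measure the spread between these samples only, which may be technical. Replicates differed by more than counting noise, with a chi-square per degree of freedom of 35.4 to 70.2 between libraries of a group, so no library was counted as a duplicate. On the recovered reads, edgeR 4.0.16 (quasi-likelihood, TMM) called 1807 of 11239 genes, 1741 of them shared with limma, and DESeq2 1.42.0 called 2249, 1778 of them shared, with no adjusted p for 688 genes.

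Gene symbols came from a RefSeq table of assembly ASM15095v2, matched on the gene model number that IDs and locus tags share. Of 11796 IDs 9253 matched and 575 had a symbol. As a check of this match, the 14 Lhcf genes had a median percentile of 96.8 among untreated levels. The table gives symbols and no product descriptions, so the lists planned on descriptions were not run. In their place 27 lists of symbols were written after the symbols and before any fold change was seen, and all had at least 5 measured members. Lists were tested with camera in limma (preset correlation 0.01, two-sided, adjusted over 27 lists), with an estimated correlation and with fry as alternatives. Lists and genes encoded by the plastid or mitochondrial genome were not analysed here, since the tables used do not mark them.

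Genes are named by a rule set before the data were examined. It takes the 12 genes with the largest changes in each direction among called genes whose groups do not overlap, the leading called members of each list (the 2 with the smallest adjusted p in each direction and the largest change), the Lhcx, alternative oxidase and superoxide dismutase genes whatever their result, and 3 called IDs without a name in each direction. Having a symbol stood in for having a description, and a mean of 10 CPM of recovered reads for the level minimum, both settled before fold changes were seen. The rule also covered nitrate reductase, nitrite reductase and violaxanthin de-epoxidase genes whatever their result, but these were not searched for. As applied, it took 85 genes, 79 of them called. Genes outside it are marked as named after their values were seen.

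Alternatives fixed before the data were examined were another scaling, limma without trend and robust, no and stricter filters, pseudocounts of 0.1 and 5, a replicate block, a fold minimum and each library left out. The count tests, TMM and total-count scaling and the fit without untreated A and tetracycline B were added after seeing the data. The analysis was tested on data simulated from these libraries with 11567 genes and 3 libraries per group, of which 50 genes were changed at each of 4 folds and 20 more were lowered together as 1 list: limma recovered 8% of genes changed 1.5-fold, 66% at 2-fold, 92% at 4-fold and 98% at 8-fold, and called 12 of 11347 unchanged genes, 7.36% of its calls, those in the lowered list included. None of the other 27 lists was called there, but genes were drawn independently of each other. In the real data the estimated correlation was 0.330 for the light-harvesting list, 0.368 for chaperones and 0.195 for photosystem genes. The simulation therefore does not show how the list test behaves for such lists. Plots were drawn with matplotlib 3.10.9.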

Results

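Transcript levels were measured by RNA sequencing in wild-type cells of the marine diatom Phaeodactylum tricornutum, a unicellular alga with a red-algal-type plastid. Cells were left untreated in 3 samples and received tetracycline hydrochloride at 4 mg/L in 3 samples. Tetracycline is an antibiotic that binds the small subunit of bacterial-type ribosomes, a class that includes those of plastids. The labels give 24 h of light for all 6 samples. Libraries held 15806015, 16469252 and 17330330 reads over genes in untreated A, B and C, and 17620230, 17582209 and 18328956 in tetracycline A, B and C. Untreated A and tetracycline B stood apart from the rest: 600 and 634 of the 11796 genes were at 0 in them, against 179 to 297 in the other 4 libraries, and 33 and 52 genes were at 0 there while averaging at least 50 in the other libraries. On log2 values each library correlated on average more with its own group, by the least in tetracycline C (Pearson r of 0.955 against 0.945). Tetracycline C correlated more with untreated C (0.961) and untreated B (0.949) than with tetracycline B (0.935), though most with tetracycline A (0.974).

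The single comparison, treated against untreated cells, asks which transcripts differ under the antibiotic. Transcripts of the light-harvesting antenna had the lowest median of the 27 gene lists tested, at a log2 fold change of −2.80. With p adjusted over all genes tested, 18 of 24 light-harvesting genes were lower with tetracycline and none was higher. Of 6 genes of the photosystems and photosynthetic electron transport, 5 fell, and 8 of 15 chaperone genes rose. Of 11505 genes tested, 1785 (15.5%) changed, 815 higher and 970 lower (limma, adjusted p under 0.05), and 921 of them changed at least 2-fold, 434 higher and 487 lower. Of the 25 genes that fell at least 8-fold, 12 were light-harvesting genes. None of the 20 genes that rose at least 8-fold has a gene symbol, but only 574 of the 11505 genes tested have a symbol.

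**Figure D1:**
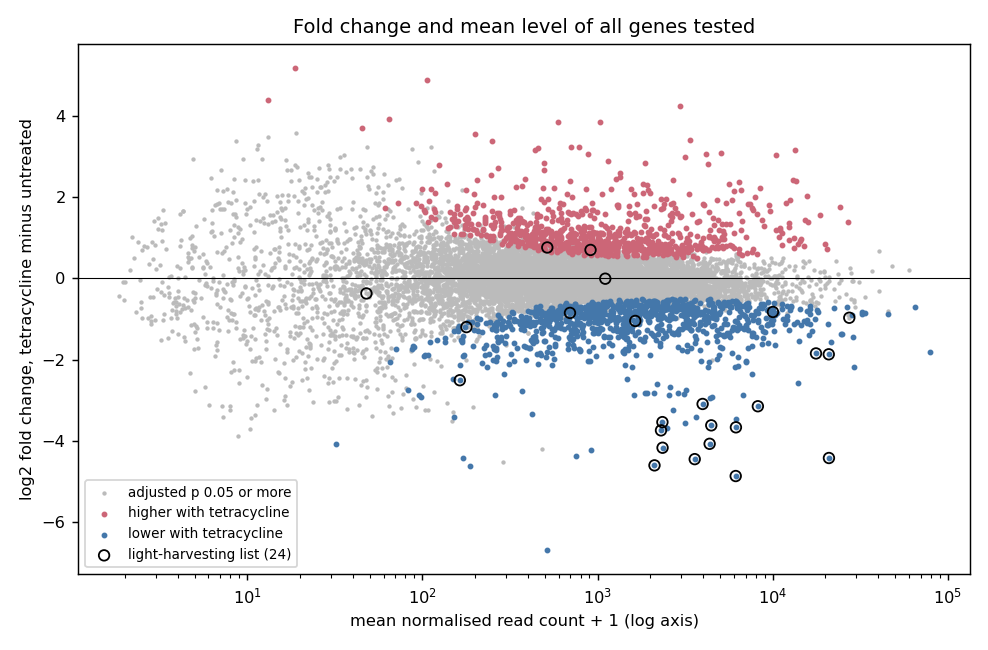
Log2 fold change, tetracycline minus untreated, against the mean normalised read count plus 1 (log axis) for the 11505 genes tested; each point is a gene, coloured by whether it was higher, lower or neither at an adjusted p under 0.05 in limma, and circles mark the 24 light-harvesting genes. Of the circled genes, 18 fell, and the lowest lies at −4.87.

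Lhcf genes encode the main fucoxanthin-chlorophyll antenna proteins. Lhcf4 (Phatr3_J25168) fell 29.2-fold, from a normalised read count of 11879 ± 3649 (SD, n = 3) in untreated cells to 427 ± 213 (SD, n = 3) with tetracycline (log2 fold change −4.87 ± 0.32 SE, adjusted p = 8.8e-06 in limma). Lhcf8 fell 24.3-fold, Lhcf3 21.9-fold and Lhcf5, the most abundant of these, 21.4-fold, from 39944 ± 17191 to 1987 ± 1379 (SD, n = 3 each). Lhcf6, Lhcf7, Lhcf2, Lhcf14 and Lhcf1 fell with log2 fold changes of −4.17, −3.74, −3.67, −3.62 and −3.54. Among Lhcr genes, which encode red-algal-type antenna proteins, Lhcr11 fell 16.8-fold and Lhcr4 8.87-fold. In each of these 11 genes every treated library lay below every untreated one, which the naming rule required of them. Among all genes tested, 34.5% did not overlap between the groups. Members of the family are similar in sequence, and how reads shared between them were assigned is not given in the sources used here, so the values of single members are uncertain. Summed over its 14 measured members, the Lhcf family took 0.960% ± 0.302 (SD, n = 3) of reads in untreated cells and 0.185% ± 0.0625 (SD, n = 3) with tetracycline, 5.19-fold less, and the 5 Lhcr genes took 0.173% ± 0.00920 and 0.0269% ± 0.00657 (SD, n = 3 each), 6.43-fold less. For both sums the two-sided exact permutation p was 0.1, the smallest that 3 against 3 samples can give.

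Lhcx genes, whose products act in photoprotection, did not pass the test. Lhcx1 stood at 35536 ± 10660 and 19256 ± 9040 (SD, n = 3 each; log2 fold change −0.97, adjusted p = 0.084 in limma), and Lhcx3 at 1102 ± 167 and 1111 ± 289 (log2 fold change −0.01, adjusted p = 0.98 in limma). Lhcx4 stood at 379 ± 91.0 and 653 ± 202 (log2 fold change 0.76, adjusted p = 0.094 in limma). On all 6 libraries, Lhcx4 passed in DESeq2 on the recovered reads (0.78, adjusted p = 0.0494). With a replicate block Lhcx4 passed in limma (0.76, adjusted p = 0.0463) and in edgeR (0.77, adjusted p = 0.0458). It also passed without tetracycline B (1.05, adjusted p = 0.0233 in limma) and without both untreated A and tetracycline B (1.16, adjusted p = 0.0290 in limma), and without tetracycline A, Lhcx1 passed at −1.29 (adjusted p = 0.0329 in limma). Over the 19 alternative fits the adjusted p ranged from 0.0233 to 0.263 for Lhcx4 and from 0.0329 to 0.257 for Lhcx1. Whether the Lhcx and Lhcf genes differed in response was not tested.

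As a set, the light-harvesting list stood lower than other genes (camera in limma, preset correlation, adjusted p = 1.96e-11 over 27 lists; adjusted p = 0.474 with an estimated correlation). Judged gene by gene, 18 of its 24 members fell against 77 of 550 other genes with a symbol. With p adjusted over the list alone, 20 fell and 2 rose: Lhcx4 (0.76) and Lhcr8 (0.70, named after its value was seen). Falls were smaller in the abundant Lhcf10 (−1.85), Lhcf15 (−1.87) and Lhcf11 (−0.83), named after their values were seen. Its median was −3.33, −2.62 and −2.32 in tetracycline A, B and C against the untreated mean, and −3.08 in a fit without untreated A and tetracycline B.

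**Figure D2:**
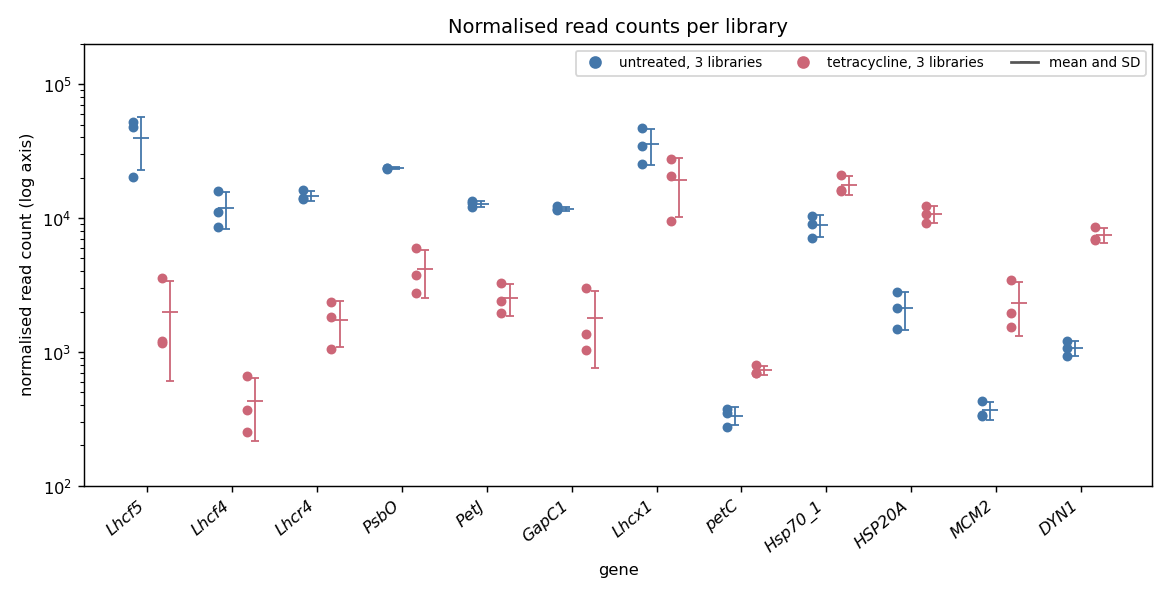
Normalised read counts on a log axis for 12 genes in the 3 untreated and the 3 tetracycline libraries; points are libraries, and the bar beside them gives the mean and SD. Lhcf5, Lhcf4, Lhcr4, PsbO, PetJ and GapC1 lie lower in every treated library, the Lhcx1 groups overlap, and petC, Hsp70_1, HSP20A, MCM2 and DYN1 lie higher.

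The 6 photosystem and photosynthetic electron transport genes, 5 lower and 1 higher, had a median of −2.06. PsbO, a subunit of the oxygen-evolving complex, fell 5.98-fold, from 23687 ± 249 to 4162 ± 1629 (SD, n = 3 each), and OEE3, of the same complex, fell 7.12-fold. PetJ, cytochrome c6, fell 5.15-fold, from 12789 ± 700 to 2535 ± 668 (SD, n = 3 each). The other members that fell, named after their values were seen, were PsbM (−1.75) and AtpC, a subunit of the plastid ATP synthase (−1.10). In the opposite direction, petC, the Rieske protein of the cytochrome b6f complex, rose 2.20-fold, from 333 ± 51.1 to 729 ± 57.4 (SD, n = 3 each; adjusted p = 0.0037 in limma). The list was lower than other genes (camera in limma, adjusted p = 0.00239), with an adjusted p = 0.474 with an estimated correlation. None of the 12 genes of tetrapyrrole and chlorophyll synthesis passed the test, with a list median of −0.23 (adjusted p = 0.367 for the list, camera in limma).

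Chaperone and heat shock genes moved the other way, with 8 of 15 higher and none lower, and a median of 0.71. HSP20A, a small heat shock protein, rose 5.16-fold, from 2135 ± 667 to 10728 ± 1545 (SD, n = 3 each; log2 fold change 2.37 ± 0.22 SE, adjusted p = 3.1e-05 in limma), HSP20 rose 3.15-fold and HSP20C 2.87-fold. The other 5 that rose, named after their values were seen, were Hsp70_1 (1.00), HSP90 (1.00), CPN60_1 (0.97), HSP70F (0.71) and 1 of the 2 GrpE genes (0.71). HSP20B, named after its value was seen, stood at 8174 ± 2969 and 5895 ± 759 (SD, n = 3 each). It did not pass (log2 fold change −0.42, adjusted p = 0.25 in limma). Summed, the 4 HSP20 genes took 2.34-fold more of the reads with tetracycline. Together the 15 genes took 0.343% ± 0.0816 of reads in untreated cells and 0.688% ± 0.0919 with tetracycline (SD, n = 3 each; two-sided exact permutation p = 0.1, the smallest possible). The list was higher than other genes (camera in limma, adjusted p = 0.00239), with an adjusted p = 0.491 with an estimated correlation. Without untreated A and tetracycline B together, 5 of the 15 genes rose, and the list's adjusted p was 0.0150.

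Carbon metabolism held changes in both directions. Of 23 genes of glycolysis and gluconeogenesis, 10 fell, 3 rose and 10 did not pass (adjusted p = 0.144 for the list, camera in limma). GapC1, a glyceraldehyde-3-phosphate dehydrogenase, fell 7.26-fold, from 11754 ± 403 to 1797 ± 1044 (SD, n = 3 each), and PPdK, pyruvate phosphate dikinase, fell 2.54-fold. GAPN, a non-phosphorylating glyceraldehyde-3-phosphate dehydrogenase, rose 2.91-fold, from 1545 ± 338 to 4427 ± 123 (SD, n = 3 each). Of 14 genes of the tricarboxylic acid cycle and pyruvate dehydrogenase, 4 fell and 1 rose (adjusted p = 0.191 for the list, camera in limma), and pDLDH1, a dihydrolipoamide dehydrogenase, fell 5.55-fold. In fatty acid synthesis, desaturation and elongation, 7 of 25 genes fell and 2 rose (adjusted p = 0.191 for the list, camera in limma). FABFa, a 3-oxoacyl-ACP synthase, fell 10.1-fold, from 764 ± 95.2 to 83.2 ± 47.5 (SD, n = 3 each), and FABI, an enoyl-ACP reductase, fell 3.20-fold, whereas ACS4 rose 3.01-fold. Of 8 genes of photorespiration and glycine cleavage, 3 fell and none rose (adjusted p = 0.129 for the list, camera in limma), among them PGP_1, a phosphoglycolate phosphatase, by 1.15 on the log2 scale. In amino acid and nitrogen metabolism, 5 of 21 genes fell, GLNA (glutamine synthetase) by 0.87 on the log2 scale among them, and 2 rose. That list had a median of 0.12, a mean of 0.05 and a downward test (adjusted p = 0.900, camera in limma).

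**Figure D3:**
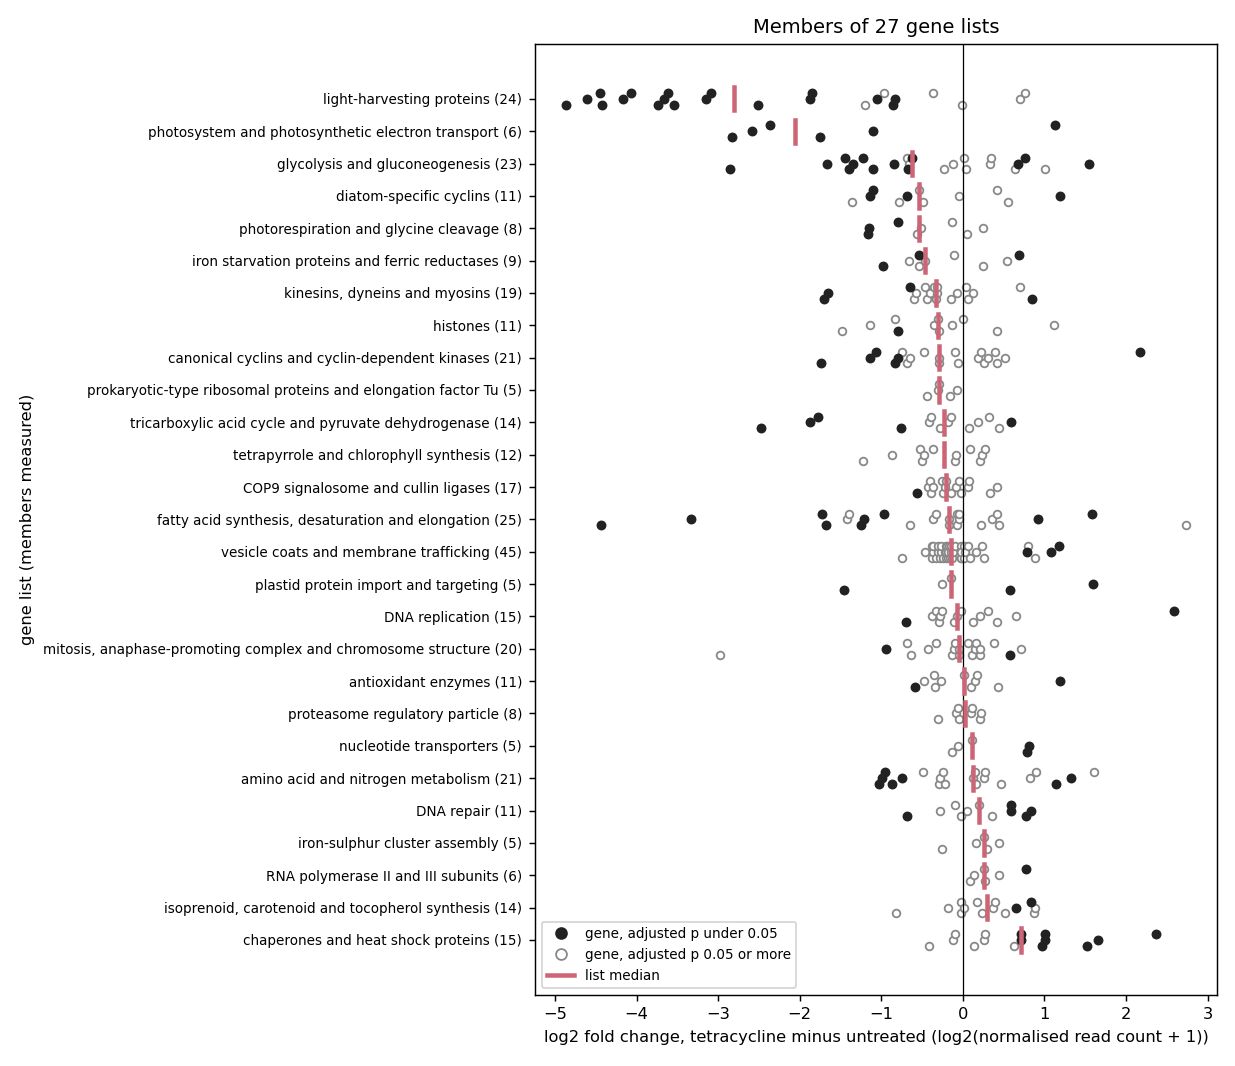
Log2 fold change, tetracycline minus untreated, of each measured member of the 27 gene lists; filled points are genes with an adjusted p under 0.05 in limma over all genes tested, open points the others, and bars the list medians. Light-harvesting and photosystem lists have the lowest medians, −2.80 and −2.06, and chaperones the highest, 0.71.

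Among DNA replication genes, MCM2 (Phatr3_J18622), a subunit of the replicative helicase, rose 5.99-fold, from 365 ± 56.5 to 2312 ± 1009 (SD, n = 3 each; log2 fold change 2.58 ± 0.27 SE, adjusted p = 5.8e-05 in limma). MCM3, of the same complex, fell by 0.69 on the log2 scale (adjusted p = 0.037 in limma), a call lost when any library other than tetracycline C was left out, at adjusted p between 0.0604 and 0.114 in limma. The other 13 genes of the list did not pass, and the list had a median of −0.07, a mean of 0.12 and a downward test (adjusted p = 0.991, camera in limma). Of 21 canonical cyclins and cyclin-dependent kinases, 5 fell and 1 rose (adjusted p = 0.191 for the list, camera in limma): CYCA/B_1 (−1.14) and CYCP1 (−1.06) were among those that fell. The gene that rose was hCDK2 (2.17, adjusted p = 0.0107 in limma), which missed the threshold without tetracycline A (2.01, adjusted p = 0.0519 in limma; 0.000866 to 0.0629 over 19 alternatives) and whose neighbour in RefSeq order, Phatr3_J42538 (named after its value was seen), rose by 1.69. Of 11 diatom-specific cyclins, 3 fell and 1 rose (adjusted p = 0.191 for the list, camera in limma), with dsCYC10 falling from 16138 ± 1372 to 7504 ± 1961 (SD, n = 3 each). SMC2, a condensin subunit, fell by 0.94 on the log2 scale, in a list of 20 mitosis, anaphase-promoting complex and chromosome structure genes with 1 lower and 1 higher (adjusted p = 0.695 for the list, camera in limma). Of 19 kinesins, dyneins and myosins, 3 fell and 1 rose (adjusted p = 0.129 for the list, camera in limma).

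In plastid protein import and targeting, Albino3, a thylakoid membrane insertase, rose 3.02-fold and secA fell 2.74-fold. That list of 5 held 2 higher and 1 lower and had a median of −0.14, a mean of 0.07 and an upward test (adjusted p = 0.900, camera in limma). Of 11 antioxidant enzymes, 1 rose and 1 fell, with a median of 0.01, a mean of 0.003 and a downward test (adjusted p = 0.991 for the list, camera in limma). Gsr_2, a glutathione reductase, rose 2.28-fold, from 2684 ± 504 to 6069 ± 662 (SD, n = 3 each), while the superoxide dismutases SOD1 (−0.35, adjusted p = 0.43 in limma) and SOD2 (−0.26, adjusted p = 0.38 in limma) and the alternative oxidase AOX1 (−0.43, adjusted p = 0.13 in limma) did not pass. Outside the lists, DYN1 rose 6.99-fold, from 1073 ± 141 to 7500 ± 971 (SD, n = 3 each), and its neighbour in RefSeq order, Phatr3_J47505, named after its value was seen, rose by 1.66 on the log2 scale. ATPase1-P5 rose 3.05-fold. Among IDs with no symbol, Phatr3_J39572 rose 18.9-fold, from 292 ± 66.2 to 5595 ± 1536, and Phatr3_EG00707 fell 18.6-fold, from 1745 ± 460 to 100 ± 47.1 (SD, n = 3 each).

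Other lists were not called, with adjusted p for the list from camera in limma. Isoprenoid, carotenoid and tocopherol synthesis had 2 of 14 genes higher (0.145), DNA repair 4 of 11 higher and 1 lower (0.191), RNA polymerase II and III subunits 1 of 6 higher (0.191) and nucleotide transporters 2 of 5 higher (0.263). Histones had 1 of 11 genes lower (0.191), and iron starvation proteins and ferric reductases 2 of 9 lower, FRE5 among them by 0.98 on the log2 scale, and 1 higher (0.244). Vesicle coats and membrane trafficking had 3 of 45 genes higher and none lower, but a median of −0.14, a mean of −0.03 and a downward test (0.347). Sec23, a coat protein of vesicles leaving the endoplasmic reticulum, rose 2.26-fold. The COP9 signalosome and cullin ligases had 1 of 17 lower (0.227). No member of the prokaryotic-type ribosomal proteins and elongation factor Tu (5 genes, 0.222), iron-sulphur cluster assembly (5 genes, 0.401) or proteasome regulatory particle (8 genes, 0.900) passed the test.

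Scaling to total reads in place of the deposited scaling moved the median log2 fold change of all genes from −0.0071 to 0.13 and turned the split of calls to 1161 higher and 652 lower, and 806 genes were called by limma without its trend and robust options, 1006 without tetracycline A, 1130 without untreated C, 1172 without untreated A and 974 without untreated A and tetracycline B together. Of the 79 called genes that the naming rule takes, 21 lost the call when 1 of the 6 libraries was left out.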

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

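Alternatives added after seeing the data are the count tests, TMM and total-count scaling and the fit without untreated A and tetracycline B together. The 1785 changed genes (815 higher, 970 lower) became 806 (403 and 403) in limma without trend and robust, 921 (434 and 487) with a log2 fold change of at least 1, and 974 (449 and 525) without untreated A and tetracycline B together, where fewer samples were fitted. Leaving out 1 library gave 1006 to 1774 changed genes, 463 to 793 higher and 543 to 1015 lower, with the lowest count without tetracycline A (1006), then untreated C (1130) and untreated A (1172), and 511 genes higher without tetracycline B. Of the 974 and 806 genes, 918 and 770 were shared with the 1785. Other settings stayed within 1.5 times: 1729 to 1826 genes over filters and pseudocounts, 1806 with median rescaling, 1776 with TMM, 1807 with edgeR and 2249 with DESeq2. Total-count scaling gave 1813 genes, 64.0% of them higher against 45.7% with the deposited scaling.

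No pairing by the letters A, B and C was seen: deviations from the group means correlated at −0.07, −0.10 and 0.14, and only the C libraries correlated best with their own letter. Untreated A and tetracycline B stood apart under different letters, which can hide a pairing, so a shared origin of the samples is not excluded. With a replicate block 1580 genes were called (726 higher, 854 lower), and among named genes Lhcx4 gained the call with it (0.76, adjusted p = 0.0463 in limma; 0.0458 in edgeR with the block) and 10 lost it in limma.

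Lists called went from 3 to 0 with an estimated correlation (adjusted p = 0.474 for light-harvesting and photosystem genes and 0.491 for chaperones), 12 with fry's directional test and 24 with fry's mixed test, neither of which compares a list with other genes. Leaving out 1 library gave 3 to 5 lists, the 5 without untreated A, where photorespiration (adjusted p = 0.0417) and histones (0.0276) passed. With the preset correlation the adjusted p in limma over 18 settings was 3.25e-14 to 1.53e-09 for light-harvesting, 0.00110 to 0.0106 for photosystem and 0.000319 to 0.0156 for chaperone genes, and the medians were −3.08 to −2.52, −2.22 to −1.87 and 0.54 to 0.85. Chaperone genes called higher went from 8 to 5 in limma without trend and robust and to 5 without untreated A and tetracycline B. No named gene or list changed direction past the threshold. Of 79 called named genes, 51 kept the call in all 19 fits, and 28 lost it in at least 1. The cause of these shifts was not tested. Leaving out plastid- and mitochondrion-encoded genes from the scaling was not run, since they are not marked in the tables used. In simulated libraries of this depth and spread 8% of 1.5-fold changes were recovered. Far fewer genes were changed there than were called here, which makes the adjusted threshold stricter. That share therefore does not carry over to the real data, where small changes may still be missed.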

Other observations

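The genes given in this paragraph lie outside the lists, were chosen after their values were seen and were not run under the alternatives, so they stand as single genes and for no pathway. SMP1 (Phatr3_J44694), with the highest mean of the untreated libraries though not of the treated ones, fell from 123048 ± 34630 to 35098 ± 11422 (SD, n = 3 each; log2 fold change −1.82, adjusted p = 0.0015 in limma). Tpt3, a triose phosphate transporter, fell by 2.81 on the log2 scale, from 3257 ± 376 to 481 ± 178 (SD, n = 3 each; adjusted p = 1.6e-05 in limma), and Tpt1, of the same family, had a log2 fold change of −1.02 (adjusted p = 0.0033 in limma). Rpe, ribulose-phosphate epimerase, fell by 2.60, from 3743 ± 326 to 627 ± 156 (SD, n = 3 each; adjusted p = 1.0e-05 in limma). MASP1 fell as well (−2.02, adjusted p = 2.0e-05 in limma), whereas Ras1, a small GTPase, rose by 1.13, from 1221 ± 32.0 to 2676 ± 206 (SD, n = 3 each; adjusted p = 0.00048 in limma).

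Across genes, which are not independent, log2 fold changes of adjacent genes in RefSeq order correlated at a Spearman rho of 0.114 over 8123 pairs (permutation p = 0.001, the smallest that the permutations drawn can give; Benjamini-Hochberg adjusted p = 0.0025 over 5 distances). For genes 2, 3, 5 and 10 apart rho was 0.0367, 0.0226, 0.00781 and 0.0125 (adjusted permutation p = 0.0025, 0.0533, 0.248 and 0.159). Deviations within groups correlated between adjacent genes at 0.0236 to 0.0881 in the 6 libraries.

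The tests of the paragraphs that follow were chosen after the results they bear on were seen, except the counts over splits of the samples. Of the 10 splits of the 6 libraries into 3 and 3, 1 gave as many changed genes, 1 as many higher and 1 as many lower, the real one each time. The real split called 1785 genes, 815 higher and 970 lower, and the highest of the other 9 called 0 in limma (up to 595 genes at an unadjusted p under 0.05, and 0 in edgeR). As many lists were called in 2 of the 10 splits, 3 in the real one and at most 3 in another. With 10 splits no share under 0.05 can be reached. The light-harvesting list was called in 4 of the other splits, at an adjusted p in limma of 0.000542 or more against 1.96e-11, the chaperone list in 2, with a lowest adjusted p of 0.00135 against 0.00239, and the photosystem list in 0. Part of any difference between treatments stays in those splits and widens the spread within their groups. Neither their gene counts nor their list calls are therefore a measure of chance alone.

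The fall of the light-harvesting list (median −2.80) was set against 3 technical explanations. Median, TMM or total-count scaling moved the median by at most 0.14 on the log2 scale. Such scalings shift all genes of a library alike, and total-count scaling moved the median of all genes from −0.0071 to 0.13. The small move shows only that the choice among these scalings does not make the fall. Reads moved between similar family members would leave the family total in place, but the summed list fell by 2.08 on the log2 scale, with a fall of at least 1.33 in every pairing of a treated with an untreated library. Without untreated A and tetracycline B the median was −3.08, so the list's fall does not rest on them. A response to the antibiotic is a hypothesis that may account for this fall relative to other genes and was not tested.

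Untreated A and tetracycline B stood apart, lying at 57.3 and 36.8 on the second principal component (26.5% of variance) against −27.9 to −13.8 in the other libraries. Fewer reads cannot account for this: 33 and 52 genes were at 0 there while averaging at least 50 elsewhere, where counting noise at their depth leaves under 1. Fewer distinct RNA molecules behind the reads would widen the spread of low genes most. Over genes above 0 in all 6 libraries, since the genes at 0 had singled these libraries out, the ratio of the SD to that of the group's other libraries was 1.27 for genes averaging 50 to 200 against 0.988 over 1000 in untreated A, and 1.48 against 1.23 in tetracycline B, a difference of at least 0.249. Fewer molecules may thus account for part of the spread, as a hypothesis found on the same data, and differences between cultures were not tested.

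MCM2 rose by 2.58 on the log2 scale apart from other replication genes. Reads from its neighbours in RefSeq order are argued against, since these flanking genes stood at −0.54 and −0.17. Genes without a RefSeq match have no place in that order, so reads from such a neighbour stay open. A general rise of replication genes is argued against too, since the other 14 had a median of −0.089, with 0 higher and 1 lower. Without untreated A and tetracycline B MCM2 stood at 2.37. A regulation of MCM2 of its own under the antibiotic may remain as a hypothesis, and a second transcript over the same locus, read from either strand, stays open as untested.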
